A study of Mus musculus with 24 samples.

How the data were processed

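RNA from whole lung of mice killed at 6 months of age was hybridised to Affymetrix expression arrays, 1 array per mouse sample. Per the labels' protocols, RNA was extracted with QIAzol and RNeasy columns, only RNA with an integrity number above 8.5 was used, and 700 pg of total RNA per sample was amplified and biotin-labelled with the GeneChip Pico kit. Per the submitters' processing notes the values were made with Affymetrix Expression Console and RMA (robust multi-array averaging: background correction, normalization and summary of the probes of each probe set). Versions, and whether all arrays were processed together, are not given in the sources used here. The deposited values are on a log2 scale. No coordinate is given here, and a genome build entered only through the gene lengths of a single check.

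The table has 24 columns. The 20 arrays that carry values were used: 6 from wild-type mice given vehicle, 4 from wild-type mice given sildenafil, 5 from Marfan mice given vehicle and 5 from Marfan mice given sildenafil. The other 4 columns belong to arrays titled as failing quality control (2 wild-type sildenafil, 1 Marfan vehicle, 1 Marfan sildenafil); they held no values and were not used. The labels name the samples by group and a running number, give no sex, litter, scan date or batch, and do not pair the samples. The running numbers follow the groups, so a batch that followed the order of the arrays and the groups cannot be told apart. Nothing states that each array came from a separate animal beyond the planned 6 per group, so p-values measure the spread between these samples.

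Of 29129 table entries, 6923 were controls and 22206 were transcript probe sets; 19572 of these have 1 gene symbol in the platform annotation, 2634 have none listed there and 0 have several. Each gene was represented by its probe set with the highest mean, which left 19505 genes. The medians of the deposited arrays ran from 5.32 to 6.45 log2 units, so the arrays did not share 1 distribution as a between-array normalization would give. The plan made before the data were examined took the deposited values as they were; because of this spread the main values were instead quantile-normalized over the 20 arrays, and the deposited values without that step became an alternative. The 4 groups were fitted together, 1 mean per group and 16 residual degrees of freedom, with limma 3.58.1 (lmFit, then eBayes with a variance trend) in R 4.3.3. Every limma p-value is two-sided and adjusted by Benjamini-Hochberg over the genes of its comparison, with a threshold of 0.05.

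There were 7 comparisons: Marfan against wild-type under each treatment, sildenafil against vehicle in each genotype, the difference between the 2 sildenafil effects (the interaction), and the genotype and sildenafil effects averaged over the other factor. Gene lists for matrix, vessel, airway, alveolar, immune, stress, metabolic and adjoining-tissue genes were fixed before the data were examined. Of 33 lists, 32 had at least 5 measured members and were tested; the erythrocyte list had 4 and was not. A list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists, and again with the correlation estimated from the data. Fry instead tested whether a list changed at all, without reference to other genes, in 1 direction and, as its mixed test, in either direction per member. Counts given as adjusted over the list alone use only that list's members. They make no allowance for the 32 lists and 7 comparisons, so that some such passes would arise by chance. Camera at a preset correlation understates the spread of genes that vary together from mouse to mouse, which is why the p-value with an estimated correlation is given beside each call.

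Genes were named by a rule fixed beforehand: up to 10 genes per direction past the threshold, or, as here, the 5 per direction with the smallest unadjusted p, said not to pass, and up to 4 members of each list with the smallest p. Genes called dim lay in the dimmer 50% of all genes by their mean. Predicted genes, receptors of smell and taste, small RNAs and antigen receptor segments were skipped. Genes that fell outside it are said to have been chosen after their values were seen. Pde5a, which encodes the enzyme that sildenafil inhibits, was to be named in every case. Fbn1, the gene mutated in Marfan syndrome, and Xist are not analysed here, so the planned sex covariate used 3 Y-linked genes alone.

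On simulated arrays with 200 changed genes among 19505, the same code called 29.9% of changes of 0.5 log2 units, 83.6% of 1 and 98.5% of 2 for Marfan against wild-type under vehicle. For the interaction the shares were 8.96%, 50.7% and 95.5%, and for the averaged sildenafil effect 61.2%, 100% and 100%. The number of arrays limits the precision: the median standard error of a log2 difference was 0.16 for Marfan against wild-type under vehicle, 0.24 for the interaction and 0.12 for the averaged effects.

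Alternatives planned beforehand were fits of only the groups compared, no variance trend, array weights, median centring, cyclic loess, leaving out the dimmer 50% of genes, all transcript probe sets, Y-linked and erythrocyte expression as covariates (the second from 4 genes), an added minimum change of 1.5-fold, an adjusted p under 0.10, an estimated correlation or fry for the lists, and leaving out each array in turn. The deposited values without further normalization, each array's deposited median as a covariate, the list tests under other normalizations and with the Y-linked covariate, and brightness together with an estimated correlation were added after the data were seen, and Marfan sildenafil array 9 was singled out then too. Regroupings of the arrays used 100 draws with a fixed seed. Genomic gene lengths, used in 1 check, came from the reference table of the GRCm38.p6 assembly. In the covariate checks and the check on gene length an explanation counted as excluded when over 50% of a list's change was left, by more than its standard error; that margin was added after the values were seen.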

Results

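Expression was measured in lungs of 6-month-old wild-type mice and of mice with Marfan syndrome, an inherited disorder of connective tissue caused by mutations of fibrillin-1, a building block of elastic fibres. Mice of both genotypes had drunk water with vehicle or with sildenafil, an inhibitor of the cyclic GMP-degrading phosphodiesterase 5, since they were 6 weeks old. The groups held 6 wild-type vehicle, 4 wild-type sildenafil, 5 Marfan vehicle and 5 Marfan sildenafil arrays, whose numbers run on over the groups, so that an array number names 1 array. The deposited median per array was 5.66 ± 0.19 (SD, n = 6) log2 units in the wild-type vehicle group. It was 6.05 ± 0.14 (n = 4) in the wild-type sildenafil, 6.03 ± 0.13 (n = 5) in the Marfan vehicle and 6.06 ± 0.28 (n = 5) in the Marfan sildenafil group, so that the control group was the dimmest before normalization between arrays. The median of 23 background probe sets ran from 2.56 to 3.28 log2 units per array. Y-linked genes were low on 2 of 6 wild-type vehicle, 1 of 4 wild-type sildenafil, 2 of 5 Marfan vehicle and 1 of 5 Marfan sildenafil arrays.

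Within groups, the SD of the difference between a pair of arrays over all genes ran from 0.32 to 0.63 log2 units (41 pairs). Marfan sildenafil array 9 stood apart from the other 19. Its score on the first principal component, which held 18.3% of the variance, was 73.8, against -9.04 to 9.11 for the others. On this array 191 genes lay over 2 log2 units above the median of the other arrays and 24 lay as far below it. The highest such counts on any other array were 9 and 8. The dim Arg1, an arginase of alternatively activated macrophages, lay 6.18 log2 units above the median of the others, Mmp12, the macrophage elastase, 5.83, and the dim Saa3, an acute-phase protein, 5.12. Gpnmb lay 4.98 and the dim Trem2, a lipid receptor of macrophages, 3.98 above it. The fibrinogen gene Fgg lay 5.13, Slc26a4 5.07, Awat1 4.96, Mmp7 4.87 and the keratin gene Krt5 4.45 above it. The genes named here for array 9 were chosen after their values were seen. The alveolar macrophage list was 1.57 and the cytokine list 1.75 log2 units higher there than the mean of the other arrays. The endothelial list lay at -0.87, the alveolar type 1 list at -0.75 and the cardiac muscle list at -2.57. All comparisons include this array unless stated.

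**Figure D1:**
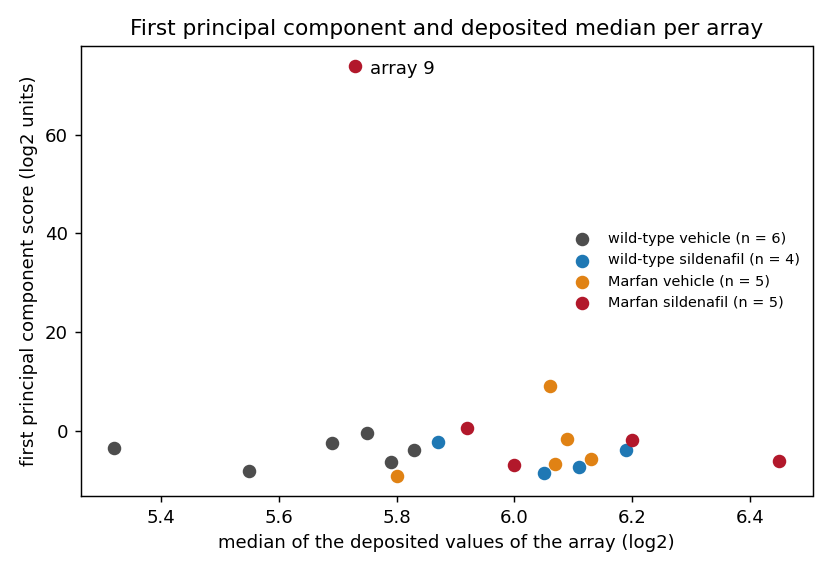
Score on the first principal component (log2 units, vertical axis) against the median of the deposited values (log2, horizontal axis) for each of the 20 arrays, coloured by group. Array 9 sits at 73.8 while the other 19 lie between -9.04 and 9.11, and the wild-type vehicle arrays occupy the dim side, from 5.32 to 5.83.

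The first comparison asked how Marfan lungs differed from wild-type lungs without drug. Genes of the elastic fibre were higher in Marfan vehicle lungs in 22 of 23 measured members. The list mean was 7.36 ± 0.10 (SD, n = 5) against 7.14 ± 0.18 (n = 6), a difference of 0.22 log2 units. Among them Loxl1, a cross-linker of elastin, was 0.55 ± 0.16 (SE) higher, Ltbp3, which binds latent TGF-beta, 0.45 ± 0.15 and Efemp1, a fibulin, 0.32 ± 0.13. Collagens and other fibrosis-associated matrix genes were 0.21 higher on average, in 19 of 26 members, and 0.12 higher without Marfan vehicle array 20. They included Col6a2 (0.51 ± 0.13), Col6a1 (0.49 ± 0.14), the fibronectin gene Fn1 (0.62 ± 0.21) and the basement membrane collagen gene Col4a2 (0.53 ± 0.19). Camera gave an adjusted p = 7.17e-06 for the elastic fibre list, and adjusted p = 0.594 with an estimated correlation. The collagen list stood at adjusted p = 1.55e-05, and adjusted p = 0.728 with an estimated correlation. Col6a1 and Col6a2 passed when adjusted over the list alone (2 of 26 members, against 0 of 23 for the elastic fibre list), and 0 members of either list passed over all genes. With array brightness as a covariate the elastic fibre difference was 0.14 (adjusted p = 0.0518).

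Under vehicle the mesothelial list was also higher in Marfan lungs, by 0.32 log2 units and in all 7 members, among them the dim Msln (0.66 ± 0.24), Lrrn4 (0.57 ± 0.22) and Upk3b (0.54 ± 0.22). Its camera adjusted p = 0.0085 became adjusted p = 0.79 with an estimated correlation. Surfactant-producing alveolar type 2 genes averaged 0.11 higher in 12 of 15 members, with Lpcat1, an enzyme of surfactant lipid synthesis, at 0.26 ± 0.11, and were not called with median centring (adjusted p = 0.761). There their mean was -0.077 and the median gene lay at -0.128, so that the list stood 0.051 above it. Lower lists were neutrophils (-0.19, 9 of 12 members, S100a8 -0.53 ± 0.27), ciliated cells (-0.11, 12 of 15) and oxidative phosphorylation (-0.082, 17 of 23). Camera's adjusted p was 0.028 for alveolar type 2 cells, 0.038 for neutrophils, 0.0482 for ciliated cells and 0.028 for oxidative phosphorylation. In the same order the adjusted p was 0.795, 0.795, 0.886 and 0.886 with an estimated correlation. No member of these 5 lists passed when adjusted over the list alone. The mesothelial call ended without Marfan vehicle array 24 and with array brightness as a covariate (0.11, adjusted p = 0.68), where oxidative phosphorylation turned to 0.035. Leaving out 1 array ended the calls of alveolar type 2 cells (array 15, 16, 18, 20 or 22, means down to 0.076), neutrophils (15, 17, 18 or 20, up to -0.045) and oxidative phosphorylation (16, 18, 20 or 24, up to -0.039). Leaving out other arrays made the differences larger, for neutrophils (-0.30 without array 13, -0.31 without 14), oxidative phosphorylation (-0.125 without 21) and ciliated cells (-0.18 without 17). The ciliated cell call ended without any 1 of arrays 1, 5, 6, 8, 12, 13, 14, 15, 16, 20 and 24 (means up to -0.061).

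Among single genes, Esm1 (endocan, a proteoglycan secreted by endothelium) stood at -0.96 ± 0.21 in Marfan vehicle against wild-type vehicle lungs. Aebp1, a collagen-binding matrix protein, stood at 0.71 ± 0.12 (SE), from 7.92 ± 0.25 (SD, n = 6) to 8.63 ± 0.18 (n = 5). Mapkbp1 was 0.49 ± 0.11 higher, Mis18a, a centromere protein, lay at -0.46 ± 0.11 and Hpf1, a partner of the ADP-ribosylating enzyme PARP1, at -0.63 ± 0.16. The dim genes Frmd5, Adam23, Oosp2, F11 and Creb3l3 completed the 10 with the smallest p. None of them passed. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 0.116, Aebp1) and 1221 at an unadjusted p under 0.05, where 975 would arise by chance. Without Marfan sildenafil array 9, which belongs to neither group but enters the shared estimate of the spread, Aebp1 and Gpc3 passed at adjusted p = 0.047. Gpc3, a cell-surface proteoglycan chosen after its value was seen, stood at 0.54 ± 0.09. Aebp1 also passed with array weights (adjusted p = 0.0285).

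**Figure D2:**
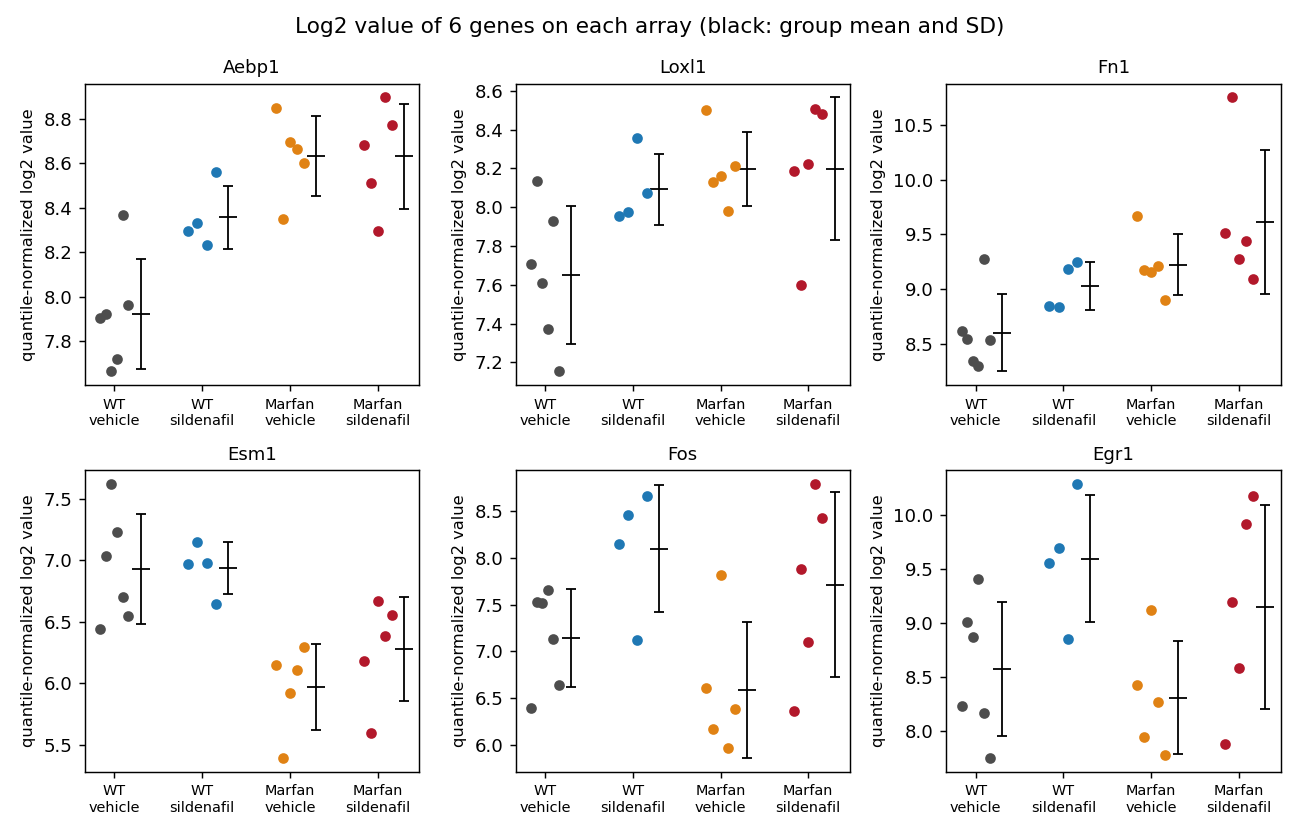
Quantile-normalized log2 value (vertical axis) of 6 genes on each array of the 4 groups (horizontal axis), with the group mean and SD in black. Aebp1 averages 7.92 in wild-type vehicle and 8.63 in Marfan vehicle lungs, Esm1 6.93 and 5.97, while Fos and Egr1 lie higher on average in both sildenafil groups than in the vehicle group of the same genotype.

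In Marfan lungs, sildenafil was compared with vehicle. Matrix proteases and their inhibitors averaged 0.37 log2 units higher under sildenafil (24 of 29 members), among them the dim collagenase gene Mmp13 (1.30 ± 0.51), Mmp19 (1.08 ± 0.41) and the lysosomal protease Ctsb (0.41 ± 0.15). Without array 9 the list averaged 0.16 (22 of 29 members, adjusted p = 0.00471, and adjusted p = 0.297 with an estimated correlation), Mmp13 0.55, Mmp19 0.41 and Ctsb 0.21. Immediate early genes, which are transcribed within minutes of a stimulus, averaged 0.24 higher (13 of 18 members), with Fos at 1.12 ± 0.39 and Egr1 at 0.84 ± 0.36. Their mean was 0.25 without array 9. Oxidative phosphorylation genes lay at -0.097 (19 of 23 members lower), and at -0.16 without array 9. Camera's adjusted p was 4.67e-05 for proteases, 0.0215 for immediate early genes and 0.016 for oxidative phosphorylation. With an estimated correlation these became adjusted p = 0.384, 0.963 and 0.963. The immediate early call ended on leaving out any of Marfan sildenafil array 12 and Marfan vehicle arrays 21, 23 and 24 (means down to 0.12), and the mean was 0.35 without Marfan vehicle array 22. That of oxidative phosphorylation ended without any of Marfan sildenafil arrays 8, 11 and 12 and Marfan vehicle arrays 21 and 22 (to -0.054).

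Cytokines and chemokines were also higher in sildenafil-treated than in vehicle-treated Marfan lungs (0.35, 20 of 25 members), with the dim Il6 at 0.70 ± 0.28, Il1b at 0.60 ± 0.26 and Nfkbia, an inhibitor of NF-kappaB, at -0.32 ± 0.10. Il6 averaged 3.44 in Marfan vehicle lungs, close to the background, whose medians reached 3.28, so that the size of its change is uncertain. So were cholesterol synthesis (0.17, 13 of 15 members, Msmo1 0.32 ± 0.12 and Idi1 0.32 ± 0.13) and cell cycle genes (0.18, 14 of 21). Camera's adjusted p was 0.00168, 0.00168 and 0.0237 for these 3 lists, and adjusted p = 0.963 with an estimated correlation for each. All 3 calls ended without array 9, where the means were 0.0029, 0.099 and 0.054 and Il6 stood at 0.32, and that of cell cycle also without array 8 (0.105), 22, 23 or 24. No member of the 6 lists called in this comparison passed when adjusted over the list alone. The genes with the smallest p included Frrs1, a ferric reductase, at 0.95 ± 0.18, Rgl1 at 0.55 ± 0.13 and Vim, the intermediate filament of mesenchymal cells, at 0.41 ± 0.10. On the lower side were Atg101, a factor that starts autophagy, at -0.59 ± 0.12, Nop10, a protein of small nucleolar particles, at -0.37 ± 0.08 and the histone H4 gene H4c8 at -0.80 ± 0.20. Nrn1 stood at -0.61 ± 0.15 and Rabepk at -0.47 ± 0.12, and the dim genes F9 and Slc7a3 completed the 10. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 0.252) and 1308 at an unadjusted p under 0.05.

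In wild-type lungs under sildenafil, oxidative phosphorylation genes were lower than under vehicle in 17 of 23 members. The list mean was 8.88 ± 0.11 (SD, n = 4) against 9.07 ± 0.13 (n = 6), a difference of -0.19 log2 units. The complex I subunit genes Ndufa2 (-0.47 ± 0.14), Ndufa1 (-0.46 ± 0.15) and Ndufb3 (-0.37 ± 0.10) and the complex III subunit gene Uqcrq (-0.41 ± 0.15) were among 8 members past the threshold when adjusted over the list alone, and 0 passed over all genes. Elastic fibre genes averaged 0.21 higher (19 of 23 members), with Ltbp4 at 0.71 ± 0.21, Ltbp3 at 0.50 ± 0.16 and Ltbp1 at 0.48 ± 0.16, the 3 that passed over the list alone. TGF-beta genes averaged 0.15 higher (16 of 23). Their 4 members past the threshold over the list alone were Tgfb2 (0.57 ± 0.17), Tgfb3 (0.43 ± 0.15), Tgfb1 (0.31 ± 0.11) and the receptor gene Tgfbr2 (0.27 ± 0.08). Collagens and other matrix genes averaged 0.15 higher (20 of 26), and Thbs1 (0.90 ± 0.30), Col6a2 (0.45 ± 0.14), Col6a1 (0.44 ± 0.14) and Bgn (0.41 ± 0.13) passed in the same way. By camera the adjusted p was 1.16e-06 for oxidative phosphorylation, 0.000274 for elastic fibre, 0.00341 for TGF-beta and 0.0163 for collagens. In the same order the adjusted p was 0.818, 0.719, 0.717 and 0.818 with an estimated correlation. The collagen call ended on leaving out wild-type sildenafil array 6 or wild-type vehicle array 16 or 18 (means down to 0.10). The wild-type vehicle arrays were the dim ones, and with array brightness as a covariate oxidative phosphorylation stood at -0.069 (adjusted p = 0.108) and elastic fibre at 0.13 (adjusted p = 0.0705). With the deposited values, relative to the median gene, oxidative phosphorylation stood at -0.16 (adjusted p = 0.0644).

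Endothelial genes were 0.20 higher in wild-type lungs under sildenafil (17 of 20 members), with Vwf at 0.47 ± 0.19, Cdh5 at 0.46 ± 0.19 and Plvap, a protein of capillary diaphragms, at 0.57 ± 0.15, the 1 member past the threshold over the list alone. Immediate early genes were 0.29 higher (15 of 18, 0 over the list alone), with Egr1 at 1.03 ± 0.37 and Fos at 0.95 ± 0.39. Ciliated cell genes lay at -0.21 (14 of 15 lower), where Rsph1, of the ciliary radial spoke (-0.58 ± 0.13), and Ccdc153 (-0.51 ± 0.16) were the 2 past the threshold over the list alone. By camera the adjusted p was 0.00207 for endothelium, 0.00341 for immediate early genes and 0.000491 for ciliated cells, and for each adjusted p = 0.818 with an estimated correlation. The smallest single-gene p-values on the higher side were those of Tram2 (0.54 ± 0.11), linked to collagen synthesis in the endoplasmic reticulum, the kinase gene Stk10 (0.51 ± 0.10) and Sgsh (0.65 ± 0.14), an enzyme of lysosomal heparan sulfate breakdown. On the lower side they were S100a13 (-0.56 ± 0.12), the splicing factor gene Lsm3 (-0.60 ± 0.13), Chchd7 (-0.60 ± 0.13) and Siva1 (-0.46 ± 0.10). The dim genes Krt72, Sptb and Spaca7 completed the 10. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 0.266) and 1774 at an unadjusted p under 0.05. The latter count was 1076 with array brightness as a covariate, where 975 would arise by chance, and 5324 with the deposited values. With array brightness as a covariate the endothelial difference was 0.048 (adjusted p = 0.559), the immediate early one 0.24 (adjusted p = 0.0613) and that of ciliated cells -0.49 (adjusted p = 4.62e-15, and adjusted p = 0.179 with an estimated correlation).

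**Figure D3:**
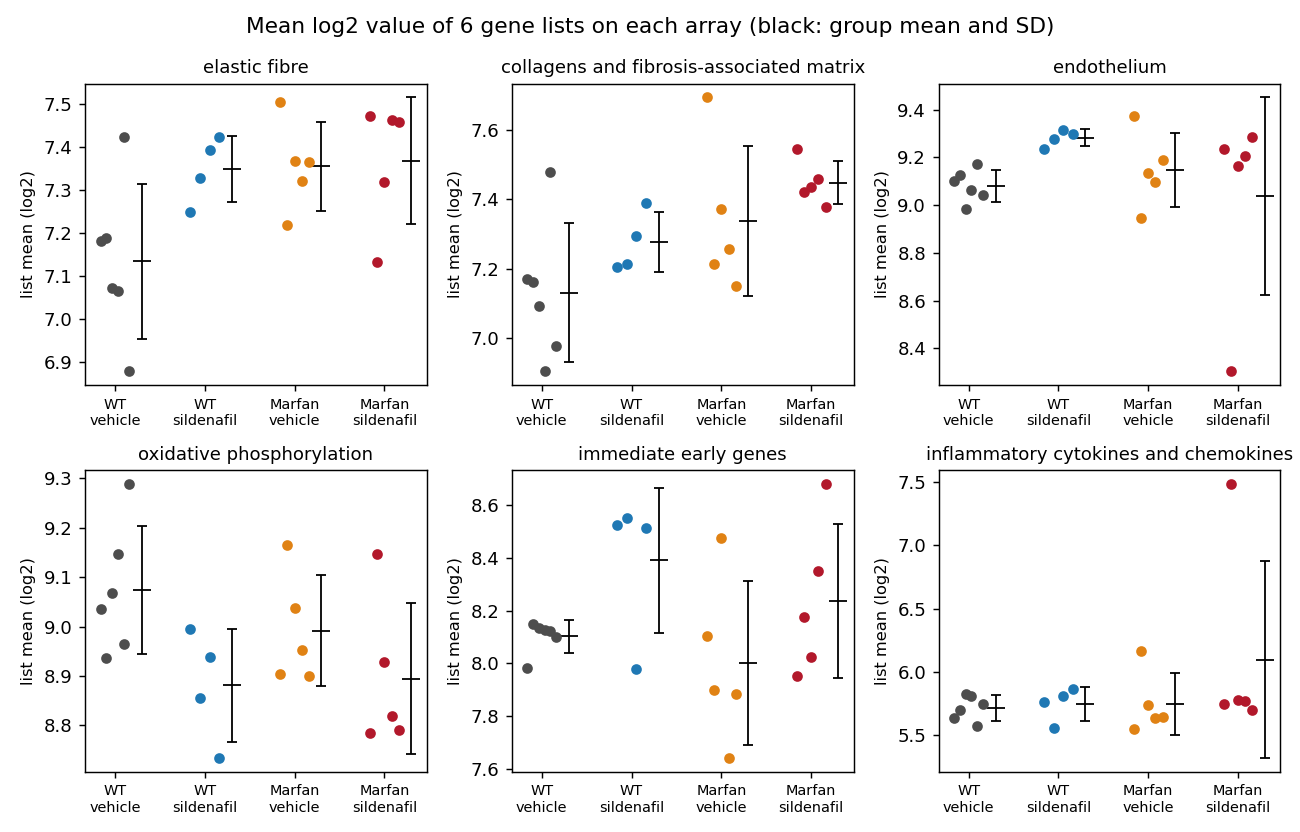
Mean log2 value (vertical axis) of the measured members of 6 gene lists on each array of the 4 groups (horizontal axis), with the group mean and SD in black. The elastic fibre mean is 7.14 in wild-type vehicle lungs and 7.35 to 7.37 in the other 3 groups, and array 9 sets the spread of the endothelial and cytokine lists in the Marfan sildenafil group.

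Under sildenafil, Marfan lungs were compared with wild-type lungs. Proteases and their inhibitors averaged 0.38 log2 units higher in Marfan lungs (24 of 29 members), with Mmp13 at 1.51 ± 0.54, the inhibitor gene Timp1 at 1.14 ± 0.43 and Ctsk, a collagen-degrading cathepsin, at 1.26 ± 0.52. Without array 9 the list averaged 0.18, Mmp13 0.76, Timp1 0.61 and Ctsk 0.48. Collagens and other matrix genes averaged 0.17 higher (19 of 26), and 0.18 without array 9. The dim tenascin gene Tnc (1.13 ± 0.29) and Col3a1 (0.61 ± 0.19) were their 2 members past the threshold over the list alone. Club and secretory airway genes were 0.38 higher (10 of 13, Scgb3a1 0.77 ± 0.37) and alveolar type 2 genes 0.093 higher (12 of 15), while immediate early genes lay at -0.16 (14 of 18 lower). By camera the adjusted p was 5.23e-06 for proteases, 0.00041 for collagens, 0.00632 for club cells, 0.0112 for alveolar type 2 cells and 0.0138 for immediate early genes. In the same order the adjusted p was 0.269, 0.669, 0.669, 0.669 and 0.701 with an estimated correlation. The calls of club cells (0.15) and alveolar type 2 cells (0.054) ended without wild-type sildenafil array 4, the second also without Marfan sildenafil array 8. Immediate early genes lost theirs without any of wild-type sildenafil arrays 1, 4 and 6 and Marfan sildenafil arrays 8 and 10 (means up to -0.084), and their mean was -0.29 without array 5 and -0.265 without array 12.

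The other 9 lists called between sildenafil-treated Marfan and wild-type lungs moved with array 9. Endothelial genes lay at -0.24 (18 of 20 lower, Plvap -0.49 ± 0.15 and Gpihbp1 -0.42 ± 0.14) with all arrays and at -0.060 without array 9. Alveolar type 1 genes lay at -0.17 and -0.017, with Igfbp2 at -0.56 ± 0.20 and Hopx at -0.36 ± 0.16 on all arrays. Alveolar macrophage genes stood at 0.37 and 0.049, with Plet1 at 0.43 ± 0.18 and Ccl6 at 0.50 ± 0.26 on all arrays. Without array 9 Gpihbp1 stood at -0.24, Igfbp2 at -0.33, Hopx at -0.13, Plet1 at 0.17 and Ccl6 at 0.21. With all arrays and without array 9, cytokines averaged 0.35 and 0.0014, T and NK cells -0.17 and -0.10, and cell cycle 0.14 and 0.019. Cholesterol synthesis averaged 0.105 and 0.037, and adipose tissue -0.27 and -0.13. Each of these 8 calls ended without array 9. The cardiac muscle list turned from -0.38 to 0.16, where camera called it in the opposite direction (adjusted p = 0.0104). With an estimated correlation, no list in that fit had a camera adjusted p below 0.206. Single other arrays also ended the calls of alveolar type 1 cells (1), T and NK cells (4 or 8), cell cycle (4 or 8), cholesterol synthesis (4, 5 or 11), cardiac muscle (5) and adipose tissue (1, 5, 6 or 12). Among them cell cycle moved to 0.070 without array 8, 0.23 without 10 and 0.215 without 12, cholesterol synthesis to 0.18 without 1 and 0.045 without 4, and cardiac muscle to -0.61 without 11. Adipose tissue moved to -0.56 without array 4, -0.12 without 5, -0.175 without 6 and -0.405 without 11. Their camera adjusted p ran from 3.62e-06 for endothelium to 0.0328 for cholesterol synthesis, and from adjusted p = 0.669 to adjusted p = 0.705 with an estimated correlation. Beside the collagen list, none of the 14 lists called here had a member past the threshold over the list alone. Tnc, Atg101 (-0.48 ± 0.12), Alas2, which starts heme synthesis in red cell precursors (-1.14 ± 0.30), and Golm2 (-0.71 ± 0.20) were among the genes with the smallest p. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 1) and 759 at an unadjusted p under 0.05, fewer than the 975 of chance.

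The interaction asked whether the sildenafil effect differed by genotype. For endothelial genes the effect was lower in Marfan than in wild-type lungs, with an interaction of -0.31 log2 units (17 of 20 members negative) and -0.13 without array 9. Vwf stood at -0.79 ± 0.26, Plvap at -0.67 ± 0.21 and Cdh5 at -0.61 ± 0.27, or -0.33 for Cdh5 without array 9. Elastic fibre genes followed at -0.20 (19 of 23 negative), with Ltbp4 at -0.63 ± 0.29, Fbln5 at -0.61 ± 0.23 (-0.37 without array 9) and Ltbp3 at -0.53 ± 0.22. Ciliated cell genes stood at 0.19 (13 of 15 positive) and 0.34 without array 9, and Rsph1, at 0.74 ± 0.19, was the 1 member of the 5 called lists past the threshold over the list alone. Club cell genes stood at 0.49 (9 of 13 positive, Scgb3a1 1.28 ± 0.50) and alveolar type 1 genes at -0.22 (11 of 12 negative), or -0.061 and no longer called without array 9. By camera the adjusted p was 5.75e-05 for endothelium, 0.00783 for elastic fibre, 0.0181 for ciliated cells, 0.0264 for club cells and 0.0225 for alveolar type 1 cells, and for each adjusted p = 0.734 with an estimated correlation. Map7d3, a microtubule-binding protein (0.74 ± 0.21), Scube1 (-0.74 ± 0.19) and the dim Krt72 (-1.23 ± 0.25) were among the genes with the smallest p. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 0.984) and 872 at an unadjusted p under 0.05. With array brightness as a covariate the endothelial interaction was -0.17 (adjusted p = 0.0601) and the elastic fibre interaction -0.12 (adjusted p = 0.189). Leaving out 1 array ended the calls of alveolar type 1 cells (array 1, 4, 9, 15, 20 or 24, means up to -0.061), club cells (1, 4, 11, 14, 15, 22 or 24, down to 0.26) and ciliated cells (4, 10, 11, 20 or 24, down to 0.12).

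Averaged over treatments, collagens and other fibrosis-associated matrix genes were higher in Marfan lungs by 0.19 log2 units, in 22 of 26 members. Tnc (0.81 ± 0.20), Fn1 (0.60 ± 0.16), Col3a1 (0.51 ± 0.13) and Col4a2 (0.39 ± 0.14) were among 8 members past the threshold when adjusted over the list alone, and 0 passed over all genes. The other 4 were Col4a1 (0.33 ± 0.12), Col6a1 (0.32 ± 0.10), Col6a2 (0.30 ± 0.10) and Col1a2 (0.28 ± 0.08). Proteases and their inhibitors averaged 0.24 higher (22 of 29, Mmp2 0.33 ± 0.12 and Timp1 0.74 ± 0.29), and 0.14 without array 9, with Timp1 at 0.47. Elastic fibre genes averaged 0.12 higher (18 of 23), with Loxl1 at 0.33 ± 0.12 and the dim Fbln2 at 0.32 ± 0.12, and 0.15 higher without array 9. Under sildenafil alone the difference was 0.021 (13 of 23) with all arrays and 0.080 (15 of 23) without array 9. Alveolar type 2 genes averaged 0.10 higher in 15 of 15 members, with the fatty acid synthase gene Fasn at 0.35 ± 0.15, the phosphate transporter gene Slc34a2 at 0.16 ± 0.08 and the surfactant protein D gene Sftpd at 0.19 ± 0.10 (0.12 without array 9). With median centring their mean was 0.011 (adjusted p = 0.208), or 0.076 above the median gene. Mesothelial genes averaged 0.22 higher (5 of 7), and Msln (0.63 ± 0.18) and Upk3b (0.46 ± 0.17) passed over the list alone. By camera the adjusted p was 3.48e-08 for collagens, 1.06e-05 for proteases, 0.000683 for elastic fibre, 0.000528 for alveolar type 2 cells and 0.00978 for mesothelium. In the same order the adjusted p was 0.252, 0.252, 0.433, 0.433 and 0.676 with an estimated correlation. With array brightness as a covariate the elastic fibre mean was 0.079 (adjusted p = 0.0941) and the mesothelial mean 0.11 (adjusted p = 0.512). The mesothelial call also ended without any of wild-type sildenafil array 5 and Marfan sildenafil arrays 11 and 12 (means down to 0.17).

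Adipose tissue genes lay at -0.27 in Marfan lungs averaged over treatments (8 of 8 lower), and immediate early genes at -0.13 (14 of 18 lower, Btg2 -0.37 ± 0.13 and Dusp1 -0.29 ± 0.13). Their camera adjusted p was 0.00258 and 0.00411, and adjusted p = 0.433 and 0.676 with an estimated correlation. Without Marfan vehicle array 23 the immediate early call ended (-0.083). The immediate early mean was -0.20 without array 5 and that of adipose tissue -0.42 without array 4, both of the wild-type sildenafil group. Endothelium (-0.089, adjusted p = 0.0161), alveolar macrophages (0.24, adjusted p = 0.00066), cytokines (0.19, adjusted p = 0.00978), cell cycle (0.11, adjusted p = 0.0126) and cardiac muscle (-0.35, adjusted p = 0.00112) were called with all arrays. With an estimated correlation the adjusted p was 0.676 for macrophages and 0.742 for the other 4. Their calls ended without array 9, where the means were 0.0028, 0.075, 0.016, 0.045 and -0.079. Under vehicle the endothelial list stood at 0.066 and the cytokine list at 0.031. Single other arrays also ended the calls of endothelium (17 or 21), cytokines (4 or 21) and cell cycle (8, 17 or 21, with 0.068 without 21). Among single genes, Aebp1 stood at 0.49 ± 0.09, Mapkbp1 at 0.43 ± 0.08, the chemokine gene Cxcl12 at 0.37 ± 0.08, and the dim genes Frmd5 and Gatm, an enzyme of creatine synthesis, at 0.75 ± 0.14 and 1.31 ± 0.26. Esm1 stood at -0.81 ± 0.16, Tmem87a at -0.26 ± 0.06, Golm2 at -0.56 ± 0.14 and Nusap1, a spindle protein, at -0.43 ± 0.11, and the dim Gprc6a completed the 10. Limma found 0 genes at an adjusted p under 0.05 (lowest adjusted p = 0.107) and 1043 at an unadjusted p under 0.05. With array weights Aebp1 and Mapkbp1 (adjusted p = 0.0147 each), Gatm (0.0206), Frmd5 (0.0332) and Esm1 (0.0459) passed.

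Averaged over genotypes, oxidative phosphorylation genes were lower under sildenafil by a mean log2 change of -0.145, in 19 of 23 members. Uqcrq (-0.35 ± 0.11), Ndufa2 (-0.33 ± 0.10), Ndufa1 (-0.33 ± 0.11), the cytochrome oxidase subunit gene Cox4i1 (-0.30 ± 0.10) and Ndufb3 (-0.28 ± 0.07) were among 10 members past the threshold when adjusted over the list alone, against 0 over all genes. Immediate early genes were 0.26 higher (14 of 18), and Fos (1.04 ± 0.28) and Egr1 (0.93 ± 0.26) passed over the list alone. The dim Fosb stood at 0.51 ± 0.20 and Zfp36 at 0.37 ± 0.13. Proteases averaged 0.22 higher (24 of 29, Mmp14 0.50 ± 0.16 and Timp2 0.27 ± 0.08), and 0.12 without array 9. Collagens averaged 0.13 higher (21 of 26), with Thbs1, at 0.76 ± 0.21, the 1 member past the threshold over the list alone. Elastic fibre genes averaged 0.11 higher (16 of 23, Lox 0.38 ± 0.13 and Ltbp1 0.37 ± 0.11) and TGF-beta genes 0.071 (17 of 23). In Marfan lungs alone elastic fibre genes stood at 0.0135 (12 of 23 higher) and TGF-beta genes at -0.0043 (11 of 23 higher), and without array 9 at 0.073 (15 of 23) and 0.0435 (12 of 23). The interaction of TGF-beta genes was -0.15 (camera adjusted p = 0.0541), and -0.10 without array 9 (adjusted p = 0.0485, and adjusted p = 0.802 with an estimated correlation). Among the TGF-beta genes, Tgfb2 (0.43 ± 0.12), Tgfb1 (0.27 ± 0.07) and Tgfbr2 (0.17 ± 0.06) passed over the list alone. By camera the adjusted p was 1.22e-06 for oxidative phosphorylation, 0.000675 for immediate early genes and for proteases, 0.00432 for collagens, 0.014 for elastic fibre and 0.031 for TGF-beta. With an estimated correlation the adjusted p was 0.794 for collagens and elastic fibre and 0.787 for the other 4. With array brightness as a covariate oxidative phosphorylation stood at -0.0786 ± 0.0616 (SE, camera adjusted p = 0.0084, and adjusted p = 0.785 with an estimated correlation). The same covariate ended the calls of elastic fibre (0.067, adjusted p = 0.206) and TGF-beta (0.044, adjusted p = 0.0763). The TGF-beta call also ended without array 6, 12, 13, 15, 16, 18, 21, 23 or 24 (means down to 0.057).

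The averaged sildenafil effect was also called for ciliated cells (-0.12, 14 of 15 lower, Ccdc153 -0.36 ± 0.11, adjusted p = 0.014), cytokines (0.19, adjusted p = 0.0242), cell cycle (0.14, adjusted p = 0.0242) and cholesterol synthesis (0.10, adjusted p = 0.014). With an estimated correlation the adjusted p was 0.911 for cholesterol synthesis and 0.988 for the other 3. These 4 calls ended without array 9, where the means were -0.045, 0.018, 0.080 and 0.071. In Marfan lungs ciliated cells stood at -0.021 with all arrays (8 of 15 lower) and at 0.12 without array 9 (12 of 15 higher, adjusted p = 0.0467, and adjusted p = 0.759 with an estimated correlation). With all arrays cytokines stood at 0.033 in wild-type lungs. Single other arrays also ended those of cytokines (5, 13, 17, 20 or 24), cell cycle (1, 8, 17, 23 or 24) and cholesterol synthesis (1 or 17, with 0.065 without 1). Il6 (0.68 ± 0.20) and Nfkbia (-0.26 ± 0.07) were the members of the cytokine list past the threshold over the list alone. Among single genes, Man1c1, a mannosidase of the Golgi, stood at 0.50 ± 0.10, Frrs1 at 0.67 ± 0.13, Prr12 at 0.48 ± 0.10, the membrane-bound transcription factor gene Creb3l2 at 0.45 ± 0.09 and Dvl3, of Wnt signalling, at 0.41 ± 0.09. Siva1 stood at -0.385 ± 0.07, Nop10 at -0.31 ± 0.06, H4c8 at -0.75 ± 0.15, Rpa3, a subunit that binds single-stranded DNA, at -0.40 ± 0.08 and S100a13 at -0.43 ± 0.09. Each of these 10 had an adjusted p = 0.0935, the lowest of the comparison. By limma 0 genes stood at an adjusted p under 0.05 and 2127 at an unadjusted p under 0.05. The latter count was 1655 with array brightness as a covariate and 3764 with the deposited values. Without array 9, 46 genes were higher and 28 lower past the threshold, all 10 of these included, and 68 genes passed with array weights.

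Pde5a, the gene of sildenafil's target enzyme, did not pass in any comparison. Under sildenafil it stood at 0.32 ± 0.20 in wild-type lungs (adjusted p = 0.654) and at 0.071 ± 0.19 in Marfan lungs (adjusted p = 0.97), against vehicle. The low value in Marfan lungs rested on array 9, where Pde5a lay at -1.29 from the mean of the other 4 arrays of its group, and without that array it stood at 0.33. The averaged difference was 0.19 ± 0.14 (SE) under sildenafil and -0.10 ± 0.14 in Marfan lungs (adjusted p = 0.641 and 0.967 by limma). Without array 9 these were 0.32 and 0.028, and the interaction of Pde5a was 0.013. With all arrays and array brightness as a covariate, Pde5a under sildenafil stood at 0.044 in wild-type lungs and 0.051 in Marfan lungs. Its averaged sildenafil difference was then 0.048. The list of nitric oxide and cyclic GMP genes (28 measured) had mean differences between -0.11 and 0.087 over the 7 comparisons, and its lowest camera adjusted p was 0.198.

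Whether sildenafil moved Marfan lungs toward or away from wild type was examined across genes. The difference of Marfan from wild-type lungs under vehicle was set against that of sildenafil from vehicle in Marfan lungs, with the shared Marfan vehicle arrays split so that no array stood on both sides. Pearson's r across genes was 0.125, where a movement toward wild type would be negative, and ran from 0.074 (without Marfan vehicle array 21) to 0.15 over the arrays left out. The permutation p was 0.09 (two-sided, 100 relabellings that gave r from -0.17 to 0.14). Without the split r was -0.28, where simulated arrays with no effect gave -0.52. The simulated genes varied independently of each other, unlike genes on real arrays, so the gap between these values is no sign of an effect. The unsplit covariance was -0.010, against -0.018 simulated, and the split one 0.0068. Genes are not independent replicates, and r lay inside the range of the relabelled arrays.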

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

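Of the tests below, those of array 9 for dimness and for another organ, and that of oxidative phosphorylation genes relative to matched genes, were chosen only after the result was seen. Array brightness as a covariate was added after the data were seen. A value was picked out when 1 sample of a group lay far from the others by Dixon's test, which chance alone does in about 1 in 20 groups, or when a gene list passed the test of the interaction. Each value is the sample's difference from the mean of the others in its group, in log2 units unless stated.

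Array 9 of the Marfan sildenafil group gave 10 of the 17 list values picked out over 132 tests and 18 of the 38 gene values over 524 tests. The 7 list values and 20 gene values on other arrays compare with 6.6 and 26.2 that chance gives over all tests. On array 9 the first principal component score was 77.3 above the mean of the others in its group. Proteases stood at 1.03, endothelium at -0.918, lung fibroblasts and pericytes at -0.502, alveolar type 1 cells at -0.773 and alveolar macrophages at 1.61. Cytokines stood at 1.74, the unfolded protein response at 0.404, the hypoxia response at 0.303, cardiac muscle at -2.71 and skeletal muscle at -0.377. Genes higher on this array were Ctsk (3.9), Mmp19 (3.33), Timp1 (2.66), Ccl6 (1.48), Fn1 (1.42), Plet1 (1.3), Frrs1 (1.08), Ctsb (0.989), Fasn (0.811) and Ltbp3 (0.299). Genes lower on it were Alas2 (-1.6), Cdh5 (-1.37), Pde5a (-1.29), Fbln5 (-1.18), Hopx (-1.12), Golm2 (-0.915), Gpihbp1 (-0.879) and Nrn1 (-0.81).

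The pattern of array 9 was weighed against a failed array and a foreign organ. Its deposited median of 5.73 lay inside the range of the other arrays (5.32 to 6.45), and its alveolar type 2 list at 11.2 lay inside theirs (10.9 to 11.3), which argues against both. A second list of macrophage genes with no overlap with the first averaged 10.3, above the other arrays (8.86 to 9.46, SD 0.135). Of its 13 measured members, 12 lay above every other array. Lgals3 lay 2.79, Ctsz 1.79, Adgre1 0.923 and Laptm5 0.77 above the others' median, while Fcgr1, at 0.165, did not exceed every other array. Each member is also expressed in the other lungs. The first macrophage list was already high on this array, so a high second list was likely and is not independent support. A lung, or a piece of it, richer in macrophages stays a candidate explanation. Fgg, Slc26a4 and Krt5, which are on none of the macrophage lists, also rose on this array, and the explanation was not tested for them. Nothing here separates a drug response of 1 mouse from an unrelated illness.

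Lower oxidative phosphorylation genes under sildenafil (-0.145 ± 0.0582 (SE), averaged over genotypes) were weighed against gene length, a wider class of transcripts and array brightness. The list median of -0.158 lay at percentile 0.06 of 10000 random lists matched on gene length and expression, but the limit of percentile 2.5 set beforehand was wrong, since genes drawn at random do not vary together as the list does (estimated correlation 0.432). Relative to matched genes on each array the mean was -0.115 ± 0.0468, too wide to tell a general effect on short genes apart. Ribosomal protein genes, another class of short and abundant transcripts, averaged -0.206 with 57 of 57 lower, so the change may belong to such transcripts as a class and not to respiration. Array brightness cannot be told apart from the averaged effect, since with it as a covariate the mean was -0.0786 ± 0.0616. In Marfan lungs alone the vehicle and sildenafil groups had like deposited medians (6.03 and 6.06). There the mean was -0.0972, and -0.088 with brightness as a covariate, so brightness accounts for little of that smaller difference. Its call, however, ended on leaving out single arrays. A metabolic effect of the drug stays open and untested.

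Higher matrix genes in Marfan lungs (0.19 ± 0.0737, collagen and matrix list averaged over treatments) were weighed against brightness, sex and cell mix. The list's adjusted p was 0.252 with an estimated correlation, so that members varying together from mouse to mouse may account for the call. With array brightness as a covariate the mean was 0.212 ± 0.0855 and with Y-linked expression 0.188 ± 0.072, which argues against each as the whole cause. With the fibroblast and pericyte score it was 0.156 ± 0.0678, too wide to exclude that part of the change follows the share of these cells, whose own list was higher by 0.0651 averaged (0.115 without array 9, adjusted p = 0.00775, or 0.236 with an estimated correlation) and by 0.132 under vehicle, as were mesothelial genes (0.22 averaged, and 0.32 in 7 of 7 members under vehicle). A higher matrix expression per cell in Marfan lungs also stays open, as a hypothesis from the same data.

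Among the other arrays, the deposited median of Marfan vehicle array 20 lay at -0.292. Lists with a single distant array were contractile smooth muscle on wild-type sildenafil 6 (0.342), T and NK cells and cell cycle on wild-type vehicle 17 (-0.557 and -0.326), and the antioxidant response on wild-type vehicle 16 (0.396). Cell cycle on Marfan vehicle 21 (0.384) and immediate early genes on wild-type vehicle 13 (-0.146) and wild-type sildenafil 5 (-0.547) were the others. On wild-type vehicle 17 the genes were Col4a2 (1.09), Fn1 (0.811), Vwf (0.786) and Siva1 (-0.288), and on wild-type vehicle 18 Bgn (-0.67), Mmp14 (-0.903), Sod3 (-0.77), Ndufa2 (0.636) and Nop10 (0.31). Marfan vehicle 20 had Col3a1 (0.882), Il6 (-0.285) and S100a9 (-1.41), and Marfan vehicle 22 had Hpf1 (-0.815), Map7d3 (0.281), Xkrx (-1.03) and Zfp36 (0.983). Single values were Ctsk on Marfan vehicle 21 (0.903), Hpf1 on wild-type sildenafil 4 (0.317), Ndufa2 on wild-type sildenafil 6 (-0.402) and Krt72 on Marfan sildenafil 8 (0.164).

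The sildenafil effect differed between genotypes, by the camera test of the interaction at a preset correlation, for endothelium (-0.309), elastic fibre (-0.2), alveolar type 1 cells (-0.215), club cells (0.493) and ciliated cells (0.191). None of the 5 passed with an estimated correlation.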

How the results depend on the processing

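The deposited values without normalization between arrays, array brightness as a covariate (alone and with an estimated correlation), the list tests under median centring and cyclic loess, those with the Y-linked covariate, and the emphasis on array 9 were chosen after seeing the data; the other alternatives were planned. Adding the 4 arrays that failed quality control was planned and not run, since their columns held no values. Of the 61 list calls, 60 kept their direction and threshold with cyclic loess, 61 with the Y-linked covariate, 53 with median centring, 50 with the deposited values, 44 with brightness, 43 without the dimmer 50% of genes and 40 with array weights. With an estimated correlation 0 lists (0 also with brightness as a covariate), and with fry's test of 1 direction 0 lists, passed in each of the 7 comparisons. Fry's mixed test passed 1 list, the collagens in the averaged Marfan effect (adjusted p = 0.0422). Leaving out 50% of the genes left 3 lists for sildenafil in Marfan lungs, 7 for the averaged Marfan and 6 for the averaged sildenafil effect. Median centring gave 13 for sildenafil in wild-type lungs, array weights 9 for Marfan against wild-type under sildenafil and brightness 3 for the interaction. Leaving out single arrays gave 4 to 10 lists for Marfan against wild-type under vehicle, 8 to 14 under sildenafil and 2 to 12 for the interaction.

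The count of 0 genes by limma became 1 with array weights and 5 with the deposited values for Marfan against wild-type under vehicle. For the averaged Marfan effect it became 5 and 2, and for the averaged sildenafil effect 68 and 3. The last was also 10 without the dimmer 50% of genes, where fewer genes were tested, and 36 at an adjusted p under 0.10. Leaving out single arrays gave 0 to 2 genes for Marfan against wild-type under vehicle, 0 to 2 for the averaged Marfan effect (2 without wild-type vehicle array 17) and 0 to 74 for the averaged sildenafil effect (74 without Marfan sildenafil array 9). The cause was not tested for these counts except where stated.

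The cross-gene correlation turned to -0.277 without the split, which is negative by construction, and ranged from 0.0742 to 0.152 over the arrays left out. Pde5a between Marfan and wild-type under vehicle turned to -0.0276 with array weights, -0.115 with median centring (0.013 above the median gene) and -0.236 with brightness, and ranged from -0.0932 to 0.112 over the arrays left out. For sildenafil in Marfan lungs it ranged from -0.0194 to 0.33, for Marfan against wild-type under sildenafil from -0.313 to 0.0344, and for the averaged Marfan effect from -0.159 to 0.028 (0.0243 with the deposited values). Its interaction ranged from -0.337 to 0.0127, with 0.00315 under array weights and 0.00676 with brightness. With the deposited values Sdhb (0.0189) and Cox5b (0.0445) turned for sildenafil in wild-type lungs, where the median gene itself lay at 0.279. For that scaling the median gene lay at 0.247 for Marfan against wild-type under vehicle, -0.237 for the interaction, 0.125 for the averaged Marfan and 0.156 for the averaged sildenafil effect, and list means are given relative to it. With median centring it lay at -0.128 for Marfan against wild-type under vehicle, -0.118 for sildenafil in wild-type lungs and 0.131 for the interaction. For Marfan against wild-type under vehicle, alveolar type 2 genes stood at -0.0766 with median centring, which is 0.0512 above the median gene, so that their turn and that of Pde5a came from the offset of this scaling. Oxidative phosphorylation turned to 0.0346 with brightness in that comparison. Cardiac muscle under sildenafil turned to 0.066 with array weights and ranged from -0.608 to 0.161 over the arrays left out, and endothelium in the averaged Marfan effect from -0.12 to 0.00277. With the deposited values Pde5a in the averaged Marfan effect (0.0243) lay below the median gene at 0.125. Sdhb and Cox5b likewise lay below the median gene at 0.279. These turns therefore came from the offset of that scaling. The cause of the remaining turns was not tested. Of the named-gene alternatives 6151 kept direction and call, 70 passed newly and 19 turned. No gene passed in the main fit of any comparison, so a kept call means that the gene still did not pass. Settings that left the log2 change as it was, such as that without a variance trend, could not turn a gene. The count of 6151 therefore says little about how stable these genes are. Signal over background limits the dim genes, since background medians reached 3.28.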

Other observations

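The fits without array 9 and the values of ribosomal genes under other scalings were chosen only after the data were seen. Without array 9, contractile smooth muscle genes were higher under sildenafil averaged over genotypes by 0.186 log2 units in 14 of 15 members, at a camera adjusted p = 0.000188, and adjusted p = 0.418 with an estimated correlation. In Marfan lungs alone the difference from vehicle was 0.254 (adjusted p = 1.44e-05, and adjusted p = 0.547 with an estimated correlation). Wild-type sildenafil array 6, kept here, lay 0.342 above the mean of the others in its group on this list. How much of the averaged difference rests on that array was not tested. Endothelial genes averaged 0.138 higher under sildenafil without array 9 in 18 of 20 members (adjusted p = 0.000188, and adjusted p = 0.36 with an estimated correlation). With all arrays, the endothelial members past the threshold over the list alone went opposite ways, Aplnr at 0.27 ± 0.09 and Gpihbp1 at -0.30 ± 0.09. Brightness was not added as a covariate to the fits without array 9. Cardiac muscle genes, which may reach lung pieces with the pulmonary veins, were called without array 9 between Marfan and wild-type lungs under vehicle (-0.319, 11 of 12 lower) and between sildenafil and vehicle in Marfan lungs (0.343, 12 of 12 higher), and turned between settings under sildenafil, at 0.161 without that array and 0.066 with array weights. Camera's adjusted p was 7.82e-06 and 3.24e-06 for the first 2, and adjusted p = 0.31 and 0.297 with an estimated correlation. Lung fibroblast and pericyte genes were called without array 9 for Marfan against wild-type under vehicle (0.132, 12 of 14 higher, adjusted p = 0.0318) and averaged over treatments (0.115, 11 of 14, adjusted p = 0.00775), with adjusted p = 0.454 and 0.236 at an estimated correlation.

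Other lists called without array 9 but not with all arrays were, for sildenafil in Marfan lungs, collagens (0.118) and ciliated cells (0.122), and in wild-type lungs neutrophils (-0.215). For Marfan against wild-type under sildenafil they were contractile smooth muscle (0.188), ciliated cells (0.223) and mesothelium (0.231). For the interaction they were TGF-beta genes (-0.104), the antioxidant response (-0.187) and cardiac muscle (0.48), and for the averaged Marfan effect contractile smooth muscle (0.12) and oxidative phosphorylation (-0.0657). Camera's adjusted p for these ran from 8.2e-08 (cardiac muscle) to 0.0485 (TGF-beta genes and antioxidant response), and with an estimated correlation from adjusted p = 0.239 (cardiac muscle) to adjusted p = 0.871 (antioxidant response).

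Ribosomal protein genes were lower under sildenafil in 57 of 57 members averaged over genotypes (-0.206), and in each setting tried: -0.287 with median centring (-0.23 relative to the median gene), -0.213 with cyclic loess, -0.23 with the deposited values relative to the median gene and -0.152 with brightness. Their mean was -0.235 in wild-type and -0.177 in Marfan lungs, or -0.134 and -0.17 with brightness. No standard error or p-value was taken for this set. Its members may vary together from mouse to mouse, and all settings reuse the same arrays, so 57 of 57 is not 57 separate observations. Ribosomal protein genes were also lower in Marfan than in wild-type lungs under vehicle (-0.114, 55 of 57 members) and averaged over treatments (-0.0854, 55 of 57). With brightness these were -0.0196 (34 of 57) and -0.0373 (44 of 57), against -0.152 (57 of 57) for the averaged sildenafil effect. The comparisons with wild-type vehicle arrays, the dim ones, therefore depend on the setting. Without those arrays, Marfan lungs under sildenafil stood at -0.0568 against wild-type lungs under sildenafil (49 of 57 lower), and at -0.055 with brightness. Sildenafil against vehicle in Marfan lungs stood at -0.177 and -0.17. The second difference was the larger, but with no standard error taken it cannot be told whether the shift was particular to sildenafil. Across the 7 comparisons, 12 of the 32 lists never passed camera with all arrays, among them 3 that passed without array 9 (lung fibroblasts and pericytes, contractile smooth muscle and the antioxidant response). The lowest adjusted p was 0.0654 for lung fibroblasts and pericytes (0.132 for Marfan against wild-type under vehicle), 0.161 for contractile smooth muscle, 0.198 for the antioxidant response and for the unfolded protein response, and 0.237 for monocytes and interstitial macrophages. It was 0.284 for interferon-stimulated genes, 0.352 for the circadian clock, 0.436 for B and plasma cells, 0.501 for skeletal muscle, 0.516 for cartilage and 0.618 for the hypoxia response. Within these lists Sod3, the extracellular superoxide dismutase gene (0.45 ± 0.12), Sod1 (-0.19 ± 0.06), Gsta4 (-0.27 ± 0.09) and the pericyte receptor gene Pdgfrb (0.42 ± 0.12) passed over the list alone for the averaged sildenafil effect, and the dim Car9 (0.49 ± 0.14) for the averaged Marfan effect.

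The arrays were regrouped at random into groups of the same sizes, 100 splits with the real one included, and each count was taken again. For genes at an unadjusted p under 0.05, fewer than 5 of 100 splits were as large for sildenafil in wild-type lungs (1774 genes, highest other split 2019, 2 of 100) and for the averaged sildenafil effect (2127, highest other 2271, 2 of 100), which share arrays. For these counts taken singly chance can be excluded at that share, but they were 2 of 21 counts with no allowance for their number. Brightness as a covariate lowered them to 1076 and 1655. Chance cannot be excluded for Marfan against wild-type under vehicle (1221, highest other 2665, 22 of 100), sildenafil in Marfan lungs (1308, 2212, 32 of 100), Marfan against wild-type under sildenafil (759, 1664, 59 of 100), the interaction (872, 2603, 49 of 100) and the averaged Marfan effect (1043, 1904, 26 of 100). Nor can it for the lists called: 7 for Marfan against wild-type under vehicle (highest other 19, 29 of 100), 6 for sildenafil in Marfan lungs (20, 96 of 100), 7 for sildenafil in wild-type lungs (14, 28 of 100) and 14 for Marfan against wild-type under sildenafil (18, 26 of 100). The interaction had 5 (19, 93 of 100), the averaged Marfan effect 12 (20, 39 of 100) and the averaged sildenafil effect 10 (18, 54 of 100). The counts of 0 genes by limma at an adjusted p under 0.05 were met by 100 of 100 splits in each comparison, which holds for any count of 0 and says nothing about chance. The highest other split gave 4 genes for Marfan against wild-type under vehicle, 123 for the interaction, 0 for the averaged sildenafil effect and 1 for each of the other 4. The 123 came from 1 split, while 2 of the 99 other splits of the interaction gave any gene, so they may point to a structure of the samples that the groups do not follow, whose cause was not tested.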
